A study of Mus musculus with 98 samples.

How the data were processed

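Full-length single-cell transcriptomes of intestinal innate lymphoid cells (ILCs), lymphocytes without rearranged antigen receptors, were compared between 2 groups. R9-ILCs were regenerated from mouse pluripotent stem cells and sorted as GFP-positive, CD45.2-positive, lineage-negative, CD127-positive cells from the gut of Rag2- and Il2rg-deficient recipients, 3 weeks after transplantation. WT-ILCs were sorted by the same gate without GFP from the gut of wild-type C57BL/6 mice aged 8 weeks. Per the labels' protocols, cDNA was made and amplified with the Discover-sc WTA Kit V2 and libraries were built with the TruePrep DNA Library Prep Kit V2. Per the submitters' processing notes, the upstream tools were bcl2fastq, HISAT2 2.1.0, SAMtools 0.1.19 and StringTie 1.3.4, with the genome build mm10.

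The authors deposited TPM (transcript abundances scaled to the same total in each column) for 23420 gene symbols in 2 tables, 1 for each group, with 98 columns in all. The TPM values of each column sum to 1e+06. Since the tables were normalized separately, a ratio of R9 over WT is a level set across tables. TPM keeps no depth, so the depth of each cell is unknown, and the number of genes at 1 TPM or more was used as the nearest view of it. Genes of the mitochondrial genome had no entry under the names searched, so the list of mitochondrial transcripts gave no value (0 members measured).

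Among the 31 WT columns, several pairs of columns held similar values in the genes that both detected. Columns of 1 group with a Pearson r above 0.8 over log2(TPM + 1) were averaged and counted as 1 cell. This r covered only genes at 1 TPM or more in both columns, and the limit was chosen after seeing the data. Pairs with the same number in their titles had r from 0.844 to 0.995, 1 column of cell 16 had r of 0.967 and 0.964 with both columns of cell 32, and the highest r of any other pair was 0.754 in R9 and 0.738 in WT. The joined columns of cells 31, 15, 24 and 9 shared only 24.0%, 26.4%, 30.6% and 31.1% of the genes detected in either column. The unjoined R9 pair with the highest r shared 32.1%, and the columns 32-1 and 32-2 shared 92.2%. That some joined columns are 1 cell is therefore an assumption. Joining left 22 WT cells, 8 of them from more than 1 column, beside 67 R9 cells. The design had counted all 31 WT columns as cells.

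Each sample was 1 cell and no animal was named in the labels, so each group was treated as 1 sample and no p-value or standard error was computed. Ratios are log2((mean TPM in R9 + 1)/(mean TPM in WT + 1)), on a scale with a pseudocount of 1 TPM, which understates differences of low genes. SDs are spreads over cells. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. Exact zeros in the tables can be failed estimates (Gapdh, a gene that every cell uses, was listed at 0 in 24 of 32, 1 of 35 and 9 of 22 cells of the 3 sets below), so genes are described as listed at 0 and not as absent. For 12 marker lists and 29 other gene lists, the median log2 ratio over members with a mean of 1 TPM or more in either group was set beside 10000 random lists of the same size matched on mean expression over 20 bins. The resulting percentile describes these cells.

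Clusters were made inside each group with the Leiden method (leidenalg 0.10.2, python-igraph 0.11.9) on genes detected in 5 or more cells, with 2000 variable genes, 10 principal components, 10 neighbours and a resolution of 1. A cluster was called "X-like" when 3 or more markers of its leading list were each detected in at least 50% of its cells and its 10 leading genes did not go against the name. No doublet caller was run, and cells with over 4000 genes were left out in an alternative instead. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are from the GRCm38 annotation, the same build as mm10, matched by gene symbol.

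R9 titles came in 2 series, without a numeric ending (32 cells) and with the ending 1 (35 cells), and WT titles ended in 1 or 2. The labels do not state the meaning of the endings, and they were treated as a possible batch. The tests, lists, markers, named-gene rule and most alternatives were fixed before the data were examined. The rule named the 12 largest ratios in each direction among genes detected in at least 50% of the cells of the higher group with 1 sign in all 4 pairings of an R9 with a WT title series, leaving out predicted, mitochondrial and ribosomal protein genes. It further named the members of the ILC and stem cell transgene lists with a mean of 10 TPM or more, up to 4 members of each other list, and the 6 largest ratios in each direction inside a cell class. Some genes that the rule names are not reported here. Textbook members of the marker lists outside this rule were picked after their values were seen.

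Alternatives varied the pseudocount, the kind of mean, the scaling, the detection limit, the filters on genes and cells, the title series and the clustering. Left out in turn, after seeing the data, were each gene's highest cell in each group and the cells with over 4000 genes, and WT columns were also kept apart or joined at a stricter r of 0.9. The steps were tested on simulated data: in a simulated R9 against WT comparison of 1764 genes, 199 of 200 changed genes had the right sign, with a median log2 ratio of 2.13 for raised and -1.82 for lowered genes where the true size was 2. In the simulated composition, 60 of 60 cells fell with their planted kind. This does not vouch for the classes of the real cells. The ILC3-like share of real R9 cells ran from 31.4% (cells of ending 1 clustered alone) to 100% (resolution of 0.5). Nor do the simulated ratios vouch for real ratios that rest on 1 cell, as several below do.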

Results

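The series profiled 67 regenerated R9-ILCs and 22 wild-type WT-ILCs from mouse intestine by full-length single-cell RNA sequencing, to set regenerated cells beside their natural counterparts. A median of 2264 genes reached 1 TPM in R9 cells (range 1187 to 6042) and 2092.5 in WT cells (793 to 7518). The 32 R9 cells without a title ending had a median of 2082.5 genes and the 35 R9 cells of title ending 1 had 2429. In 26 of those 32 cells, 1 of the 35 and 5 of the 22 WT cells, a single gene held 10% or more of all TPM, up to 44.3% for Ifngr1 in an R9 cell. The labels name no animals, so the differences have no replicate check. Where 2 log2 ratios are joined by "or", the latter leaves out each gene's highest cell in each group.

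Several ILC3 genes were seen at 1 TPM or more in most cells of both groups. Il23r, the receptor chain for interleukin 23, was detected in 60 of 67 R9 cells (89.6%, 95% interval 79.7 to 95.7) and 20 of 22 WT cells (90.9%, 70.8 to 98.9), the chemokine receptor gene Ccr6 in 89.6% and 86.4%, and Ncoa7 in 100% of both. At 10 TPM or more, Il23r was at 67.2% and 68.2%, Ccr6 at 56.7% and 63.6%, and Ncoa7 at 83.6% and 86.4%. Ccr6 was then seen in 87.5% of R9 cells without a title ending and 28.6% of those of ending 1. Kit, the stem cell factor receptor, was detected in 86.6% of R9 cells (76.0 to 93.7) and 63.6% of WT cells (40.7 to 82.8), intervals that overlap. The effector cytokine Il22 was seen in 31.3% and 27.3% of cells, while Il17a was seen in 0 of 67 and 0 of 22, which sets no limit on expression since listed zeros can be failed estimates.

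Levels of ILC3 genes lay on both sides of 0. Il23r reached 100 TPM in 47.8% of R9 cells (35.4 to 60.3) and 31.8% of WT cells (13.9 to 54.9), with log2(TPM + 1) of 5.61 ± 3.51 (SD over 67 cells) and 5.18 ± 3.33 (SD over 22 cells). Its mean TPM was 298.6 against 268.9, a log2 ratio of 0.15 across the separately normalized tables, which was 0.71 in R9 cells of ending 1 and -0.90 in those without an ending, where the median of all genes was 0.94 and -0.67. The tetraspanin gene Cd81 was lower in R9 (-1.21, and -1.42 inside the ILC3-like class of clusters), and Ccr6 was at -1.45 over all cells but at -0.26, or 0.22, inside that class, while Kit (0.39), the lymphotoxin gene Lta (0.09), Il1r1 (0.05, or 0.64), Cxcr5 (-0.09), Tmem176a (-0.52), Tmem176b (0.06) and Ncoa7 (-0.39) lay nearer to 0, and Pram1 was at 1.23, or 1.82. Of the 17 ILC3 list members used, 9 were higher and 8 lower in R9, with a median of 0.05 at the percentile 30.4 of random lists.

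Among ILC2 list members, Gata3 and Arg1 lay on opposite sides. Gata3, a transcription factor that ILC2s need at high levels and that all ILCs use, had a mean of 54.2 TPM in R9 and 0.89 TPM in WT (log2 ratio 4.87, with 5.05 and 4.67 in the R9 series without and with the ending), and was detected in 47.8% (35.4 to 60.3) and 22.7% (7.82 to 45.4) of cells. Arg1, which encodes the arginine-degrading enzyme arginase 1, was detected in 47.8% of R9 cells and 95.5% of WT cells (77.2 to 99.9), with 55.7 against 791.8 TPM. The stem cell antigen gene Ly6a (1.94) and the Notch target Hes1 (2.33, or 3.71) were higher in R9. The lipid enzyme gene Dgat2 was at -4.41, or -2.55, and Nmur1, the receptor of the nerve signal neuromedin U, at -4.75, or -0.54. The genes of the ILC2 cytokines Il13 and Il5 and the interleukin 33 receptor Il1rl1 were seen in 0 cells of either group. The ILC2 list had 7 members higher and 4 lower, with a median of 1.74 (percentile 88.8), which was -0.23 over the same members in R9 cells of ending 1, which is -1.17 relative to all genes there.

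**Figure D1:**
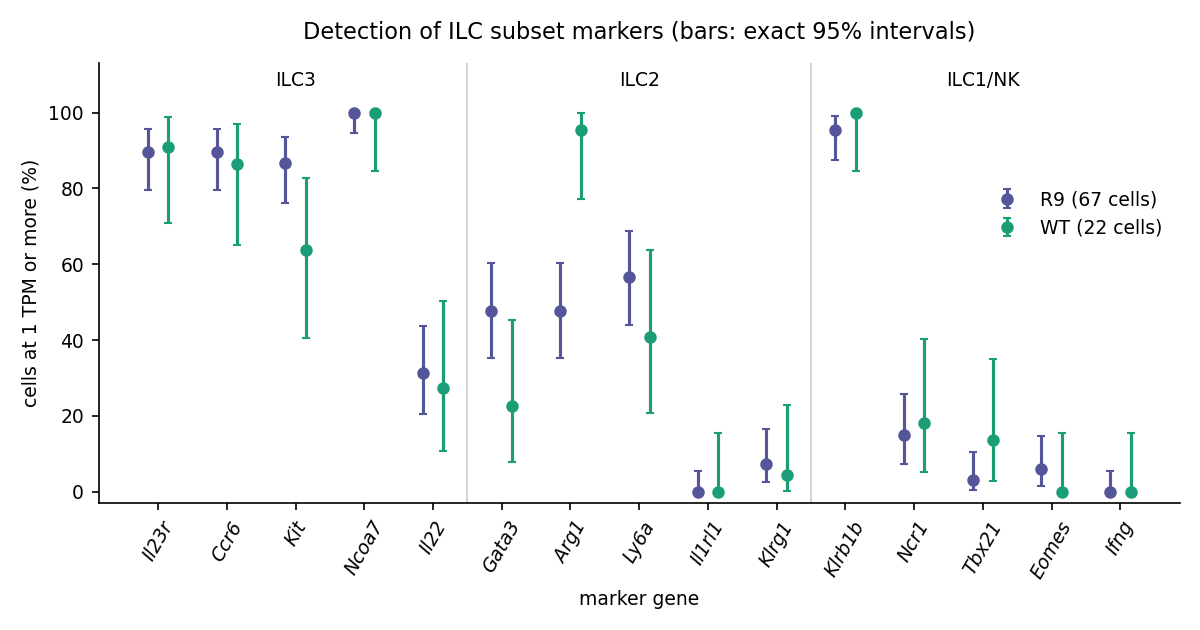
Percent of cells at 1 TPM or more (vertical axis) for ILC3, ILC2 and ILC1/NK markers (horizontal axis) in 67 R9 and 22 WT cells. Points are shares and bars exact 95% intervals. Il23r lies at 89.6% and 90.9%, and the widest gap is that of Arg1 at 47.8% and 95.5%.

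Among ILC1 and natural killer (NK) cell genes, detection ranged from 0 cells to nearly all of them. Tbx21, the transcription factor of type 1 lymphocytes, was seen in 2.99% of R9 and 13.6% of WT cells, Eomes in 5.97% and 0%, and the interferon gamma gene Ifng in 0 cells. The NK receptor gene Ncr1 was seen in 14.9% and 18.2%, and in 31.3% and 0% of the R9 series without and with the ending. Its log2 ratio of -2.65 came from 1 WT cell and was 0.96 without the highest cells, as were those of Gzmb, which encodes granzyme B (-7.84, then 0.04), the chemokine receptor gene Cxcr3 (-1.19, then 1.02) and Klrb1c (4.39 from 1 R9 cell, then 0.16). Klrb1b, a lectin-like receptor gene, was detected in 95.5% and 100% of cells at similar means (ratio -0.25), and Il2rb was at -1.25, or -0.51. The chemokine gene Ccl5 was higher in R9 (2.78), yet at -2.14 in R9 cells of ending 1. The list median was -0.63 (percentile 4.28), with 2 of 10 members higher in R9. It was -0.32 in R9 cells without an ending and -2.05 in those of ending 1. Relative to all genes these are 0.35 and -2.99, so of the 2 R9 series only that of ending 1 lay below all genes. The list also holds Ncr1, Gzmb and Cxcr3, whose negative ratios came from 1 WT cell each.

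Among genes of core ILC identity, Thy1 was seen in 44.8% of R9 and 31.8% of WT cells and Il2ra in 58.2% and 54.5%. Id2, the transcriptional repressor that all ILCs use, was detected in every cell of both groups at 3455 and 1987 TPM (log2 ratio 0.80), as was Il2rg (0.40), the cytokine receptor chain that the recipients lack. The ILC transcription factor gene Rora was at 1.13, with -0.05 in R9 cells without an ending, the gut-homing integrin gene Itgb7 at 1.45, the surface antigen gene Thy1 at 1.66, or 2.25, and Il2ra at 0.88, or 1.54. Cd7 (-2.73) and Cd52 (-1.52), both lymphocyte surface genes, were lower in R9, and Cd7 was at 1.38 TPM in R9 cells of ending 1 against 264 without an ending. The list had 10 of 13 members higher and a median of 0.80 (percentile 95.5), which is 0.17 above all genes. The median was 0.01 in R9 cells without an ending, 0.68 above all genes there. In R9 cells of ending 1 it was 0.96, only 0.01 above all genes there. Il7r (CD127) and Ptprc (CD45) belong to the sort gate.

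**Figure D2:**
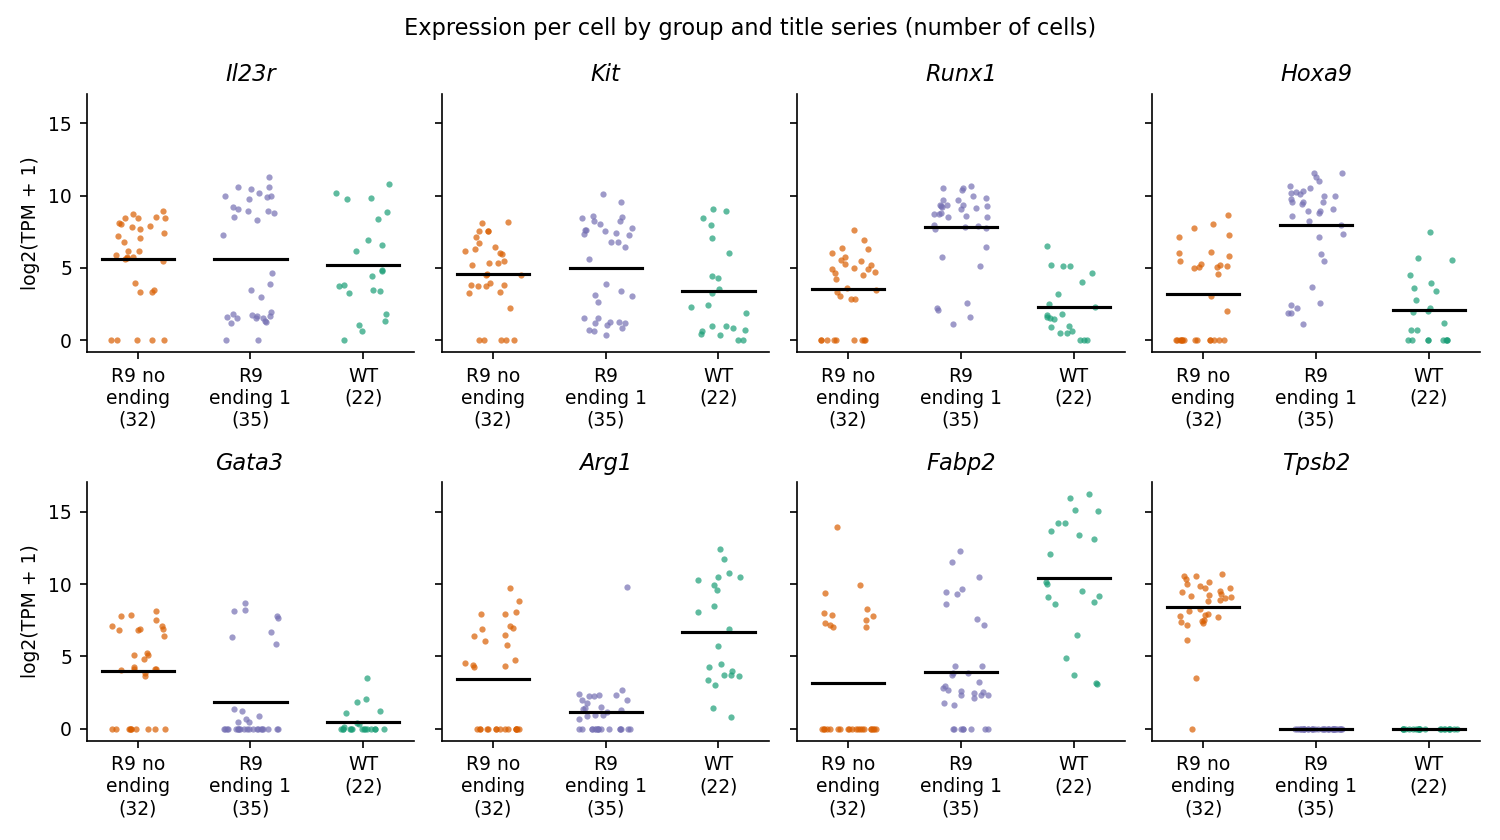
Expression of 8 genes as log2(TPM + 1) (vertical axis) in single cells of the 2 R9 title series and of WT. Each point is 1 cell and each line the mean over cells. Runx1 and Hoxa9 lie highest in the 35 R9 cells of ending 1, Tpsb2 in the 32 R9 cells without an ending, and Fabp2 and Arg1 in the 22 WT cells.

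Clustering put most cells of both groups in an ILC3-like class. In R9, 55 of 67 cells (82.1%, 70.8 to 90.4) fell in 4 ILC3-like clusters, and in WT 16 of 22 (72.7%, 49.8 to 89.3) fell in 1. The remaining 12 R9 cells and 6 WT cells formed 1 cluster each in which epithelial markers were seen as often as ILC3 markers (mean shares of 61.8% against 61.0% in R9 and 66.7% against 64.9% in WT), and these stayed unnamed. Cells of an ILC1/NK-like or ILC2-like cluster numbered 0, but the smallest clusters held 8 R9 and 6 WT cells, so a few such cells would form none and this sets no limit on their share. Taken cell by cell, the ILC3 list had the largest share of detected members of the 3 ILC lists in 67 of 67 and 22 of 22 cells. This depends on the make-up of the lists. Il13, Il5 and Ifng of the other lists were seen in 0 cells, while Tmem176b and Ncoa7 were seen in 100% of both groups. The count therefore does not show that each cell is an ILC3. Each of the 5 R9 clusters held cells of 1 title series only, so clusters inside R9 cannot be told from the series, and the CD127 gate sets which ILCs could be seen. The ILC3-like share depended on the clustering: it was 47.8% of R9 and 36.4% of WT cells with 5 neighbours, 100% of both at a resolution of 0.5, and 31.4% of R9 cells of ending 1 clustered alone.

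The genes with the largest ratios in favour of R9 included immune regulators. Fli1, an ETS transcription factor of blood cells (chromosome 9, 32422204 to 32543432), had a mean of 80.3 TPM against 1.26 in WT, a log2 ratio of 5.17, and was detected in 53.7% and 22.7% of cells. Myd88, the adaptor of Toll-like and interleukin 1 receptors (chromosome 9, 119335934 to 119340018), stood at 174.6 against 3.43 TPM (5.31), with 2.67 and 6.13 in the R9 series without and with the ending. Dars, the aspartyl-tRNA synthetase gene (chromosome 1, 128363707 to 128417416), stood at 158 against 2.72 TPM (5.42, or 6.02). Cd3g, a chain of the T cell receptor complex, was at 429.8 against 13.6 TPM (4.89), though it was detected in 50.7% of R9 and 50% of WT cells, and its ratio was 1.26 in R9 cells without an ending. N4bp2l1 (4.99), the phosphatase gene Inpp5k (4.74), Tmem55b (4.78) and Nubp2 (133.5 against 3.21 TPM) followed. For Dctn5 (6.88), Snx2 (4.86), Ppp4c (4.74) and Tram1 (4.74), over 90% of the summed R9 values came from 1 cell, and without the highest cells they were at 3.31, 2.69, 1.00 and 0.73.

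The genes with the largest ratios in favour of WT included several that gut epithelium is known to express. Fabp2, the intestinal fatty acid binding protein gene (chromosome 3, 122895072 to 122899506), was detected in 58.2% of R9 and 100% of WT cells at 465 against 13137 TPM, a log2 ratio of -4.82. Apoa1, which encodes the main protein of high-density lipoprotein (chromosome 9, 46228630 to 46230469), stood at 81.5 against 7170.4 TPM (-6.44, or -5.84), the ileal bile acid binding gene Fabp6 at -4.38 (or -6.75), Calml4 at -8.36 (or -6.11), and the keratinocyte and gut surface gene Sprr2a1 at -7.54. Arg1 (chromosome 10, 24915207 to 24927470) was at -3.80 and Pole4, a subunit of a DNA polymerase, at 110.5 against 1778.5 TPM (-4.00, or -3.22). A single WT cell held over 80% of the WT sum of Tpd52 (-5.62, or -3.45), Pigs (-5.98, or -0.89), Ccm2 (-5.89, or -1.06), R3hcc1l (-5.27, or -0.30) and Tmem30a (-5.12, which turned to 1.48). In 12 of the 24 genes, 1 cell held at least 50% of the higher group's sum, and 23 of 24 kept their sign by the mean of log2 values.

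**Figure D3:**
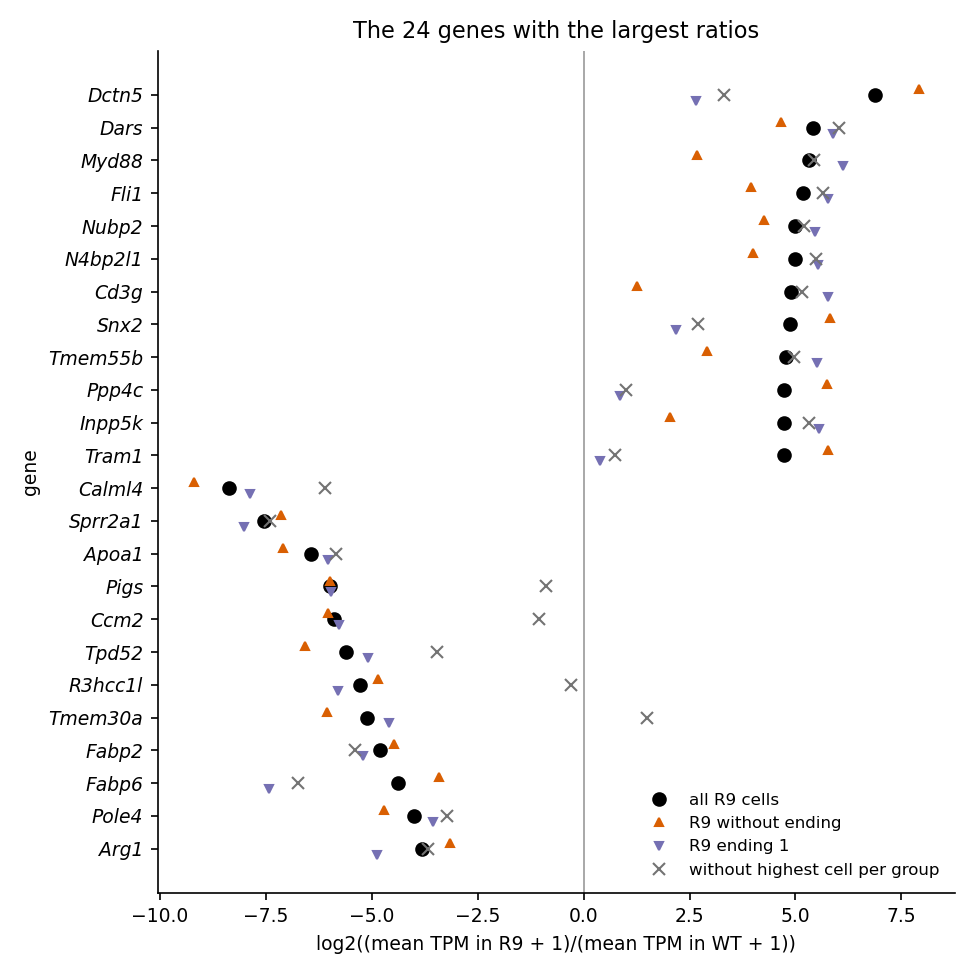
Log2 ratio of mean TPM in R9 over WT (horizontal axis) for the 24 genes with the largest ratios (vertical axis). Symbols are all R9 cells, each R9 title series, and all cells without the highest cell of each group. Tmem30a alone changes sign without the highest cells, from -5.12 to 1.48.

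The median log2 ratio over 10691 genes was 0.62, and it was -0.67 in R9 cells without an ending, 0.94 in those of ending 1 and 0.06 when each cell was scaled by common genes and 1.36 without each gene's highest cells, so list medians are read against 0.62. In 17 of 40 lists the median was at least 1 in size. Runx1 and Hoxa9, transcription factor genes used to drive blood formation from pluripotent stem cells, formed the stem cell transgene list with a median of 4.57 (percentile 99.5). Runx1 stood at 283 against 11.98 TPM (4.45) and Hoxa9 at 434.7 against 15.8 TPM (4.70, or 5.42). Runx1 reached 100 TPM in 77.1% of R9 cells of ending 1, 6.25% of those without an ending and 0% of WT cells, and its ratio was 5.31 in ending 1 and 1.296 without an ending, that of Hoxa9 5.55 and 1.64. The list of HOX and early haematopoietic genes was at 1.32 (percentile 85.8), with Meis1 at 0.97, or 2.94. The ILC precursor list was at 1.35 (percentile 91.0), with 9 of 11 members higher, among them the T cell factor gene Tcf7 (1.54, which turned to -1.90 under common-gene scaling) and Ets1 (0.98).

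Genes of other cell types differed with group and title series. Mast cell protease genes formed the list with the highest median, with Tpsb2 at 274.7 TPM, Cpa3 at 279.8 and Cma1 at 160.4, where WT cells were listed at 0 for Tpsb2 and Cpa3. The mast and basophil list had a median of 5.71 (percentile 100), which rests on the pseudocount since 5 of 6 members were listed at 0 in WT. Tpsb2 reached 100 TPM in 29 of 32 R9 cells without an ending (90.6%, 75.0 to 98.0) and 0 of 35 of ending 1 (up to 10%). The epithelial list was lowest against random lists (-1.57, percentile 0.06), with 8 of 12 members lower in R9. These included the keratin gene Krt20 (-4.17), which turned to 2.19 against WT columns of ending 1. The antimicrobial gene Reg3g was higher (2.95) but turned to -2.22 in R9 cells of ending 1. The list was at -2.17 and -2.54 in the 2 R9 series and at 0.15 against WT columns of ending 1, which is -1.51, -3.48 and -1.11 relative to all genes.

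Haemoglobin genes gave the erythroid list a median of 2.49 (percentile 99.3), with Hba-a2 at 2.42 and Hba-a1 at 8.31. Hba-a1 was seen in 16.4% of R9 and 9.09% of WT cells, and its ratio was 3.80 without the cells with over 4000 genes, 0.70 in R9 cells without an ending, and 2.03 inside the ILC3-like class, or 4.17. The T cell list was at 3.27 with 2 members used, the neutrophil list at 2.21 with 3, of which S100a8 was listed at 0 in WT, and the macrophage and dendritic list at 0.57 (percentile 53.7), with Cd68 detected in 13.4% of R9 and 0% of WT cells. The macrophage and dendritic list was at 1.38 in R9 cells without an ending, the series that held the mast cell genes, and at -2.08 in those of ending 1. The B and plasma cell list was at -2.07 with Cd79b as its 1 member, the endothelial list at -2.23 and the stromal list at 0.10, with 2 members each. Lineage markers of T, B and myeloid cells belong to the sort gate.

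The immediate early list was at 1.60 (percentile 99.8), with 1.41 in R9 cells without an ending and 0.55 in those of ending 1, where all genes were at -0.67 and 0.94. It had 19 of 21 members higher, including the growth factor response genes Egr1 (2.56, or 3.26) and Zfp36 (2.30) and the AP-1 subunit Fos (2.49), which was at -3.69 in R9 cells of ending 1. The interferon response list was at 1.37 (percentile 98.6), with 1.77 and 0.79 in the series without and with the ending. Relative to all genes in each series it was at 2.44 and -0.15. It had 15 of 21 members higher and 6 listed at 0 in WT, where Isg15 (6.14, or 7.35) had 87.9% of its R9 sum in 1 cell, Xaf1 was at 6.12 and the nucleic acid sensor gene Zbp1 was listed at 0 in WT and detected in 25.4% of R9 cells. MHC class I genes were at 0.82 (percentile 94.9; 0.16 and 1.31 in the 2 series), with 11 of 13 higher, including H2-Q7 (2.63) and the peptide loading genes Tapbp (2.19) and Tap2 (2.18, or 3.02). MHC class II genes were at 0.60 (percentile 61.2), close to the median of all genes, with 1.34 without an ending and -0.79 in ending 1. Among them were Cd74 at 0.89 and H2-Aa at -0.47, which turned to 1.03 without the highest cells.

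The 8 used members of the effector cytokine list had a median of 1.39 (percentile 90.8), 0.77 above all genes, and 5 of them were higher by 1 or more, including Tnfsf11, the RANK ligand gene (4.33, or 4.97), Tnf (1.41, or 3.93) and Il22 (1.38, or 2.73). Cytokine receptor genes were at 0.40 (percentile 45.3), with Il4ra at 4.11, or 3.47, and chemokines at 0.69 with 2 members. Cytotoxic granule genes were at -0.02 (percentile 22.1), with the granzyme inhibitor gene Serpinb9 at 4.37. Relative to all genes, the granule list was at 0.71 in R9 cells without an ending and -1.57 in those of ending 1. Gut homing and tissue residence genes were at 1.07 (percentile 89.4), with 8 of 8 higher, among them Rgs1 (2.80) and Cd69 (0.68, or 1.86). Genes of circulation and lymph node entry were at 0.09 (percentile 20.6), with Klf3 at -0.42 and S1pr4 at 0.09. The neuropeptide and nerve signal receptor list was at -0.69 (percentile 6.98), with Vipr2 at -4.08 and Ramp3 at 0.81, and the checkpoint and costimulation list at -0.55 (percentile 7.07), with Cd160 at -1.59 and Tnfrsf25 at 1.46, which was -1.18 in R9 cells without an ending.

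The glycolysis list was at 0.80 (percentile 94.3), and 0.12 and 0.17 above all genes in R9 cells without an ending and of ending 1, with pyruvate kinase Pkm at 2.22, Gpi1 at 2.14 and hexokinase Hk1 at 3.25, or 4.80. Oxidative phosphorylation was at -0.42 (percentile 10.54), at -0.43 and -1.15 relative to all genes in these series, with 11 of 18 members lower, including Cox7a2 (-1.81), against Atp5b at 1.48. Lipid and cholesterol genes were at 0.65 (percentile 31.3, with Idi1 at 2.73, or 3.38), cell cycle genes at 1.00 (percentile 74.5, with Mcm6 at 3.10, Tubb5 at 2.95 and Top2a at -3.42, or -1.16) and apoptosis genes at 0.27 (percentile 34.9, with Birc3 at 5.16 and Casp8 at -2.27, or -0.52). TGF-beta signalling genes were at 1.01 (percentile 48.4, with Smad4 at 1.74) and over the same members at -0.44 in R9 cells without an ending, 0.23 above all genes there, and the retinoid and aryl hydrocarbon receptor list was at 0.93 (percentile 44.1, with Rxrb at 4.12). Heat shock genes were at 0.07 (percentile 30.2, with Hspe1 at 0.75), ribosomal protein genes at 0.30 (percentile 74.3), housekeeping genes at 0.31 (percentile 69.2, with Ywhaz at 1.14 and Sdha at -1.61, or -0.35), nuclear retained RNAs at -2.42 (percentile 3.45, with Malat1 at -2.42, or -0.98) and sex-linked genes at -0.61 (percentile 19.2, with Xist at -5.12, or -3.61).

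Relative to the median of all genes in the same series, 7 lists lay at least 1 above it in R9 cells without an ending and at least 1 below it in those of ending 1, over the same members. These were the ILC2 (2.97 and -1.17), macrophage and dendritic (2.04 and -3.02), neutrophil (3.39 and -1.12), chemokine (1.88 and -2.71), MHC class II (2.01 and -1.73), circulation (1.18 and -1.08) and sex-linked lists (1.00 and -4.28). With members chosen again in ending 1, the neutrophil list was at 0.13.

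**Figure D4:**
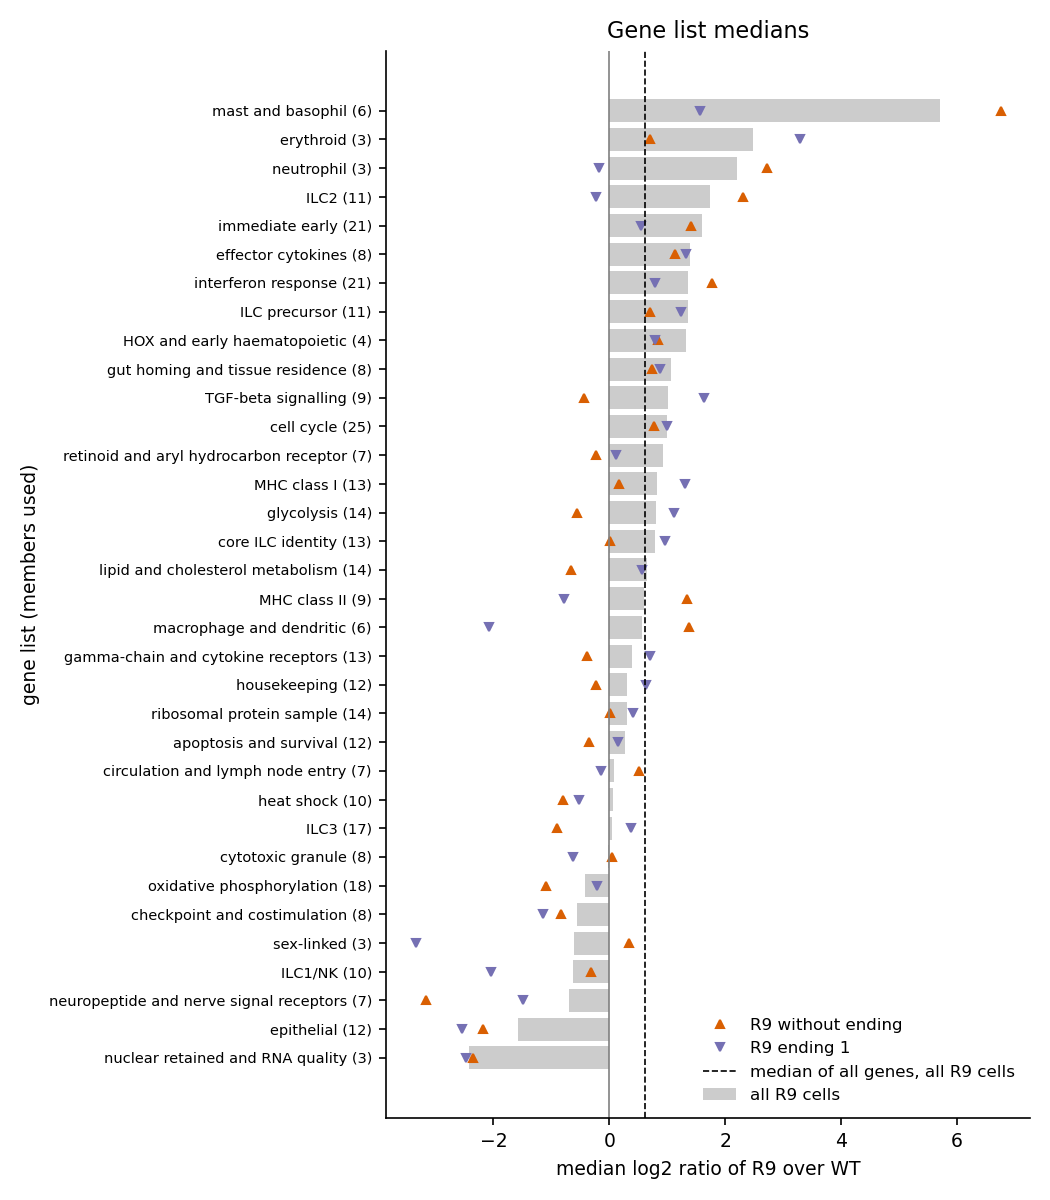
Median log2 ratio of R9 over WT (horizontal axis) for gene lists with 3 or more members used (vertical axis, number of members in parentheses). Bars are all R9 cells, triangles the 2 R9 title series, and the dashed line the median of all genes. The mast and basophil list lies highest at 5.71 and the nuclear retained list lowest at -2.42.

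Inside the ILC3-like class (55 R9 and 16 WT cells), 23 of the 24 genes kept the sign they had over all cells. The class holds most of the cells by which these genes were chosen, so this is no separate check. The largest ratios there were those of Cpa3 and Tpsb2, with 340.8 and 334.6 TPM in R9 and listed at 0 in WT, Cma1 (7.30), the calcium binding protein gene Cib1 (6.51, or 7.62), Emc6 (6.35, or 4.53) and the galectin gene Lgals1 (6.18, or 7.32). Lowest were Calml4 (-10.32, or -8.53), Sprr2a1 (-8.07), Apoa1 (-7.52, or -6.64), Pigs (-6.38, or -0.74), Ccm2 (-6.30, or -1.57) and Cox7a2l (-5.41, which turned to 0.54 without the highest cells). Other genes named above moved by 1 or more from all cells to the class, to 0.25, or -0.22, for Nmur1, 2.69 for Tmem30a, 1.55, or 2.80, for Cxcr5, -3.10, or 1.37, for Cxcr3, -0.60, or 2.17, for Cd79b, -3.42, or -1.50, for Tpd52, 9.56, or 5.07, for Dctn5, 5.61, or 4.92, for Hes1, 4.51 for Tnf, 8.14, or 7.52, for Xaf1, 5.49 for Mcm6, 5.44 for Hspe1, 2.00, or 3.62, for Cd69 and -6.26, or -4.04, for Xist. The class was held by 1 cluster of 23 cells of ending 1 and 3 clusters of 13, 11 and 8 cells without an ending in R9, and by 1 cluster of 16 in WT, so values within it carry the title series too.

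Across 10691 genes, which are not independent replicates, the mean profiles of R9 and WT cells had a Pearson r of 0.65 and a Spearman rho of 0.61. The 2 R9 title series had an r of 0.62 with each other, and of 0.58 (without an ending) and 0.60 (ending 1) with WT. Random splits of a single set into 2 parts gave a median r of 0.63, 0.60 and 0.50 for R9 without an ending, R9 of ending 1 and WT, from means over 11 to 18 cells, fewer than those behind the r between groups. WT columns of endings 1 and 2 had an r of 0.75, but many of them were joined as the same cells.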

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

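All tests in this part were chosen after the result they bear on was seen, and so were the length classes and limits used below, which followed a first look with finer classes.

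Mast cell protease genes stood in R9 cells without a title ending, where 29 of 32 cells held Tpsb2 at 100 TPM or more, beside 0 of 35 cells of ending 1, and Cpa3 and Tpsb2 averaged 279.8 and 274.7 TPM over all R9 cells. Of the Tpsb2 cells, 82.8% (24 of 29) also held the ILC3 gene Il23r at 10 TPM or more. The share was 78.1% among all 32 cells of the series. Other members of the mast and basophil list were seen less often in this series. At 1 TPM or more, Mcpt4 was seen in 8 of 32 cells and Fcer1a in 1 of 32. Hdc, Ms4a2, Mcpt1, Mcpt2 and Mcpt8 were seen in 0 of 32, though listed zeros can be failed estimates. Whole mast cells in place of ILCs stay open, since Il23r levels in mast cells were not measured. RNA of other cells could also have brought Il23r into them. Tpsb2 at this level was not shared by all R9 cells. The upper limit of the share in ending 1 is 10.003% and the lower limit in the other series 75.0%. These limits come from the counts that made the pattern, so they are no separate test. RNA from mast cells added in varying amounts stays open and cannot be told apart from expression by the cells, because the median r between the 4 mast cell genes tested lay at the percentile 48.3 of random lists and evenly added RNA would give no such correlation. The lineage gate may have removed whole mast cells but not their free RNA, and a biological difference between the R9 series stays untested.

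Epithelial genes such as Fabp2, at 13137 TPM, stood high in WT cells. Cell pairs confined to the cells with the most genes are argued against, since the epithelial list stayed at -2.09 relative to all genes without the cells with over 4000 genes. Epithelial cells in place of ILCs stay open: the CD45 and CD127 gate would remove them and Tmem176a and Tmem176b stood at 10 TPM or more in 22 of 22 WT cells, but epithelial levels of these genes were not measured, and of 17 WT cells with Fabp2 at 100 TPM or more 15 held Il23r at 1 TPM or more (lower limit 63.6%) and 11 at 10 TPM or more (lower limit 38.3%). RNA of epithelial cells added in varying amounts is a candidate explanation, as the median r between 10 epithelial genes across WT cells was 0.467 against 0.12 for random lists, yet it was 0.734 against 0.035 for 8 such genes in R9 cells of ending 1, so it does not set WT apart. The amount of such RNA could differ between wild-type and recipient gut or between preparations, which the design does not separate, and the list was at -1.11 relative to all genes when WT was held to columns of ending 1.

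Among 2274 genes seen in at least 50% of the cells of some set, the median share of cells was 50% in R9 without an ending and 68.6% in R9 of ending 1. An equal gap at every length is argued against, since the gap between the series was 0 percentage points for transcripts over 3000 nucleotides. It was -42.1 for those up to 750 (lengths were known for 95.3% of these genes). The gap widened by -42.1 points from the longest to the shortest class. In the finer classes of the first look it ran from 2.72 to -44.3 points. Loss of short transcripts in R9 cells without an ending stays a candidate explanation. A lower depth or sensitivity cannot be told apart from it. Short transcripts yield fewer reads in full-length libraries, and the depth is unknown. A few abundant transcripts that push others under 1 TPM stay open. In R9 cells without an ending, 0.25% of the values above 0 lay under 1 TPM and 10.9% under 10 TPM. Low values are thus nearly missing and the test decides nothing. No biological explanation was tested.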

How the results depend on the processing

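Leaving out each gene's highest cell, leaving out cells with over 4000 genes, keeping WT columns apart or joining them at r of 0.9, and the detection limit of 100 TPM were chosen after seeing the data. No paired analysis was possible because the title numbers name cells and no test across samples was made. Of 1750 ratios of 125 named genes over all settings, 23 changed the sign of a ratio of at least 1 in size, and of the rest 1372 moved by less than 1 on the log2 scale and 355 by more, with 55 sign changes of smaller ratios among them. For 40 list medians, 4 of 638 values changed such a sign, 533 moved by less than 1 and 101 by more, with 53 sign changes of smaller medians, and for marker shares 454 of 539 stayed within their interval, 85 moved out of it and 0 reversed. The unknown depth limits all shares of detected cells, most of all for low genes.

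Without each gene's highest cell, ratios turned to 1.48 for Tmem30a, 0.96 for Ncr1, 1.02 for Cxcr3 and 0.041 for Gzmb, as these rested on 1 cell. By the mean of log2 values Tmem30a was at 0.89. Gzmb was at 1.44 in cells with 1000 or more genes and also against WT columns of ending 2, Krt20 was at 2.19, C1qb at 3.72, Cox7a2l at 0.074 and the epithelial list at 0.15 (-1.11 relative to all genes) against WT columns of ending 1. In R9 cells without an ending, Klrb1c was at -0.26, Rora at -0.051, Tnfrsf25 at -1.18, Psmb7 at -2.21 and the TGF-beta signalling list at -0.74. In R9 cells of ending 1, Ccl5 was at -2.14, Cma1 at -0.24, Reg3g at -2.22, Fos at -3.69, Dusp1 at -0.65, Jun at -0.079 and the ILC2 list at -0.74, and the last was at -0.93 among members with a mean of 10 TPM or more. List members were chosen anew in each setting, so these medians differ from those over the same members. Scaled by common genes, Reg3g was at -0.85, Tcf7 at -1.90 and Psmb7 at -2.72. The cause was not tested.

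The number of lists with a median of at least 1 in size, 17, became 8 with a pseudocount of 10, 8 by the mean of log2 values, 7 without a filter on low values and 28 without each gene's highest cell. Detection of Il23r in R9, 89.6%, was 67.2% at 10 TPM and 47.8% at 100 TPM. The similarity of mean profiles, 0.65, was 0.83 without a filter, 0.48 among genes with a mean of 10 TPM or more and 0.74 without the highest cells. Of the 24 genes with the largest ratios, 23 had their sign by the mean of log2 values and 23 without the highest cells, and 24 in the other settings, among which the title series were part of the rule that chose them. Inside the class, which holds most of the cells by which they were chosen, 23 had it, and 22 without the highest cells. The medians of genes per cell stayed within 1 SD over cells in the settings run.

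The ILC3-like share moved with the settings. For R9 (82.1%) it was 100% at a resolution of 0.5, cell by cell, in cells without an ending and without cells over 4000 genes, 94.0% with both groups clustered after centring, 68.7% with 1000 variable genes, 47.8% with 4000 variable genes, with 5 neighbours and with both groups clustered together, and 31.4% in cells of ending 1. For WT (72.7%) it was 100% at a resolution of 0.5, cell by cell, with 4000 variable genes, in columns of ending 1 and without cells over 4000 genes, 90.9% after joint centring, 40.9% with 1000 variable genes, 39.1% with columns joined at r of 0.9, 38.7% with all 31 columns and 36.4% with 5 neighbours. The cause was not tested.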

Other observations

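The 3 tests on Runx1 and Hoxa9 and the genes named in this part were chosen after the values were seen.

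Of the lists fixed beforehand, MHC class II genes (2.01 against -1.73) and macrophage and dendritic genes (2.04 against -3.02) lay on opposite sides of the median of all genes in the R9 series without an ending and of ending 1, over the same members. Fos reached 100 TPM in 90.6% of the 32 cells without an ending and 0% of the 35 of ending 1, and the stress response genes Dusp1 and Jun in 75.0% against 5.71% and 56.3% against 14.3%. Cd74, the MHC class II invariant chain, reached 100 TPM in 100% and 11.4% of cells, H2-Aa in 56.3% and 2.86%, and the myeloid lysozyme gene Lyz2 in 81.3% and 2.86%. The complement genes C1qc and C1qb, known from macrophages, were seen at 1 TPM or more in 53.1% against 2.86% and 40.6% against 0% of cells, and in 27.3% of WT cells each. In the other direction, Fau was at 100 TPM in 28.1% of cells without an ending and 91.4% of ending 1, the proteasome gene Psmb7 in 6.25% and 71.4%, and the splicing gene Snrpe and the translocon gene Sec61g in 0% and 68.6% each. These series have no stated meaning, and the differences are given as values.

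Runx1 and Hoxa9 varied together across the 35 R9 cells of ending 1, which are cells of unknown animals and not independent replicates. The hypothesis that both may be carried on 1 introduced construct would give such a link, and the Pearson r of their log2(TPM + 1) was 0.919 (Spearman rho 0.93), above that of 99.999% of the 1755001 gene pairs in these cells. It was 0.892 without the 2 cells farthest from the median of Runx1 and 0.79 among the 27 cells with Runx1 at 100 TPM or more, 26 of which also held Hoxa9 at that level. A linear effect of genes per cell is argued against, since r was 0.921 after such a term was removed. The depth of each cell is unknown, so differences in depth themselves stay open. In R9 cells without an ending r was 0.12 over 32 cells, above 39.3% of gene pairs and so under their median, in a series where 2 cells held Runx1 at 100 TPM or more. In WT cells r was 0.67 over 22, above 98.9% of gene pairs, a lower rank than in R9 cells of ending 1 but past the limit of 95% set for cells without a construct. The sets point different ways and the hypothesis stays open. The excess over WT was larger in ending 1 but not confined to it, as the smaller of the 2 log2 ratios without an ending was 1.296. Relative to all genes, the list of the 2 genes was at 2.14 without an ending and 4.49 in ending 1. How much of the excess belongs to the group and how much to the title series cannot be told apart. The labels do not say what the endings mean. Between R9 titles and WT columns that both end in 1 the ratios were 6.89 for Runx1 and 7.78 for Hoxa9, over 35 and 10 columns, but the ending need not mean the same in both groups.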
